A study of Rattus norvegicus with 12 samples.

How the data were processed

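Poly-A RNA sequencing (paired-end) had been done on 12 libraries after OGD/R, 3 in each of the 4 groups NC, CIRBP, si-NC and si-CIRBP. The titles name the cells H9C2, but the cell line label gives rat astrocytes, so which cells were used is unclear. Each library was placed in its group by its title, which also calls it a biological replicate. The table's columns for NC and CIRBP carry the prefix ad, which the labels do not explain, and those for the other groups do not. Whether both arms used the same cells and the same way of treatment is not given in the sources used here. Expression was used as FPKM (fragments scaled to transcript length and to the mapped fragments of the library), as the authors computed it per gene and library, per the file headers. Bowtie2 2.3.3.1 and Cufflinks 2.2.1 and the mouse builds GRCm38 and mm10 are named per the submitters' processing notes, without a role for each. The gene identifiers are rat Ensembl identifiers, so which build the reads were aligned to is unclear, and no coordinates are printed. The strand setting, the annotation version and the way of counting reads shared by near-identical genes are not given in the sources used here. Genes of such families (the Mx, Ifit, Oas, Ccl, Cxcl, S100, histone, metallothionein and ribosomal protein genes, and mitochondrial genes with nuclear copies) are therefore uncertain one by one.

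The table held 18344 rows, 16618 with rat Ensembl identifiers and 1726 with identifiers of transcripts assembled by the authors, and no row was at 0 in every library. Symbols were taken from the table, where 80 names were shared by more than 1 row. The first and second principal components held 49.9% and 28.9% of the variance. Apart from values of 0, no row had the same value in any pair of libraries. FPKM hold no absolute depth, so the depth behind each value is unknown and no counting interval was computed. Ratios of values under 0.3 FPKM between libraries gathered at a modal ratio (tolerance 0.15%), which gives the depth relative to NC library 1. A value of exactly 0 in FPKM can be a failed estimate and is reported only as listed at 0.

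Groups were compared with limma 3.58.1 (eBayes with a trend) in R 4.3.3 on log2(FPKM + 1), in 14257 genes with at least 1 FPKM in 3 or more libraries (1357 of them assembled by the authors). The fit had 1 coefficient per group over all 12 libraries, with 8 residual and 2.53 prior degrees of freedom and no block for the replicate number. The p-values were two-sided and adjusted by Benjamini and Hochberg's method over all genes tested, and genes with an adjusted p under 0.05 were called. The contrasts were CIRBP minus NC, si-CIRBP minus si-NC, the first minus the second, and si-NC minus NC. A fold change is on the log2(FPKM + 1) scale and understates the change of genes with low values. Calls shared by both arms were set beside the number that independent lists of the same sizes would share, and the arms have separate controls.

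The tests, the gene lists and the rule for naming genes were fixed before the data were examined, with 1 test for counts and 1 for normalised values, of which the latter was used. The 35 lists covered stress responses, metabolism, the cell cycle, inflammation and cell type markers. Each list with at least 5 tested members, 1 row per symbol, was tested with camera of limma at a preset correlation of 0.01, adjusted over the 32 lists of a comparison. At that setting 13, 11, 6 and 14 lists were called in the 4 contrasts, and with an estimated correlation 0 in each. The estimate came from the residuals of all 12 libraries, so each list had the same value in every contrast. It was not made from only the groups compared, where camera was run at the preset correlation alone. Named genes were Cirbp and Rbm3, the 10 largest increases and 10 largest decreases of each arm (5 each between the control groups) among called genes whose 3 values of one group all lay above the 3 of the other and whose higher group had a mean of at least 1 FPKM, up to 4 called members per list with the smallest adjusted p, and the 10 genes with the largest opposite changes. Rows named only by an identifier, a clone or a provisional locus, small RNA families and names shared by more than 1 row were left out of that rule. A single gene among those that the rule took was left out of the text and is not reported here. Other list members named in the text were chosen after their values were seen.

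The fit was tested on simulated libraries with 200 changed genes, drawn with each gene's own SD per group. Of genes changed by 1 on the log2 scale it recovered 80% in CIRBP against NC, 87.8% in si-CIRBP against si-NC, 62% for the difference and 74% in si-NC against NC. Unchanged genes made up 6.4%, 65.1%, 33% and 35.2% of its calls in these contrasts, against the 5% aimed at. These shares were 0%, 55.5%, 19.3% and 18.5% where the SDs were moderated across genes. Such shares depend on how many genes change, here 200, so they do not carry over to the calls below. With 1 variance factor per group the shares were 24.1%, 36.1%, 34.3% and 37.2% with each gene's own SD, and with only the groups compared 8.67%, 14.7% and 17% for the 3 group comparisons. In the same simulated libraries, fitting only the groups compared thus lowered the share in si-CIRBP against si-NC from 65.1% to 14.7%. It fell from 35.2% to 17% in si-NC against NC but rose from 6.4% to 8.67% in CIRBP against NC. Fitting all 12 libraries together therefore held part of the excess over 5% where si groups were compared. What holds the rest was not tested. This simulation was extended after its first result was seen, and the design was kept as fixed, with the count from a fit of only the groups compared given beside each group comparison. In a second simulation of independent genes, camera called the shifted list in all of 3 contrasts and none of 200 unchanged lists, where an unadjusted p under 0.05 was found for 7, 6 and 9 of them with the preset correlation and 3, 2 and 5 with the estimated one. Alternatives were scaling to one median, no filter, no trend, a pseudocount of 0.1, the replicate number as a block, only the groups compared, each library left out in turn and stricter thresholds. After the data were seen, the following were added: library 1 of si-NC and of si-CIRBP both left out, scaling by median ratios, the mean of the smooth muscle markers as a covariate, 1 variance factor per group, and camera on only the groups compared.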

Results

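RNA sequencing libraries had been made from cells named H9C2 in the labels, a line derived from embryonic rat heart that serves as a cardiac myoblast model, after oxygen-glucose deprivation and reperfusion (OGD/R). This treatment is a culture model of ischaemia. The 12 libraries formed 4 groups of 3, labelled NC, CIRBP, si-NC and si-CIRBP after the treatment added to OGD/R. The labels call the libraries of a group biological replicates. The labels name H9C2 as the source but give rat astrocytes as the cell line, so which cells were used is unclear. Whether the NC and si-NC groups shared the same cells and way of treatment is not given in the sources used here, so a difference between them can hold more than the treatment named. CIRBP was compared with NC and si-CIRBP with si-NC, which asks how treatments aimed at Cirbp, the cold-inducible RNA-binding protein, changed the transcriptome under OGD/R. These pairs are the 2 arms below, and no library without OGD/R was used here. Summed expression ranged from 457775 to 502889 FPKM per library. Absolute depth is unknown, but the steps between low values put the depth of the other libraries at 0.843 to 1.03 times that of NC library 1.

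Cirbp (ENSRNOG00000015999) stood at 19.7 ± 0.557 FPKM in NC (mean ± SD, n = 3) and rose to 35.8 ± 1.27 FPKM in CIRBP (log2 fold change 0.83, SE 0.0652, adjusted p = 2.47e-06 with limma), with all 3 CIRBP libraries above all 3 NC libraries. In the libraries labelled si-CIRBP it was not lower than in si-NC, at 27.6 ± 1.04 against 26.7 ± 2.43 FPKM (log2 fold change 0.05, SE 0.0652, adjusted p = 0.609). The single libraries stood at 26.5, 28.6 and 27.7 FPKM against 29.0, 24.2 and 27.0 FPKM. After scaling of the libraries to one median, the same comparison gave 0.16 (adjusted p = 0.0435 with limma, against 0.0435 to 0.835 over the alternatives), a rise and not a fall. The Cirbp mRNA thus goes against the si-CIRBP label. The group is therefore named below as the libraries labelled si-CIRBP, and no direction given for it rests on a measured loss of Cirbp. The si-NC libraries also held more Cirbp than NC (log2 fold change 0.42, adjusted p = 0.00134). Rbm3 (ENSRNOG00000005387), the other main cold-induced RNA-binding protein, was at 219 ± 2.37 FPKM in NC and 228 ± 13.1 FPKM in CIRBP (log2 fold change 0.05, adjusted p = 0.386). The change passed the test after scaling to one median (0.20, adjusted p = 0.00317) or by median ratios (0.18, adjusted p = 0.00711). It was at 273 ± 0.513 FPKM in si-NC and 303 ± 3.01 FPKM in the libraries labelled si-CIRBP (log2 fold change 0.15, adjusted p = 0.031). That call was lost in a fit of those 6 libraries alone (adjusted p = 0.194), with a variance factor per group (0.278) and without the trend (0.0512). It was also lost without si-NC library 1 (0.0514), si-NC library 3 (0.0747), si-CIRBP library 2 (0.0712) or si-CIRBP library 3 (0.0788). Of the 9 tested members of the list of cold-shock RNA-binding proteins, Cirbp alone was called in CIRBP against NC (1 adjusted over the list alone, camera adjusted p = 0.343), although 5 rose after scaling to one median and 4 after scaling by median ratios, and the median of the list, -0.02, turned positive. In the other arm Rbm3 alone was called (0 adjusted over the list alone, camera adjusted p = 0.379), against 3 members after scaling to one median and 2 by median ratios.

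**Figure D1:**
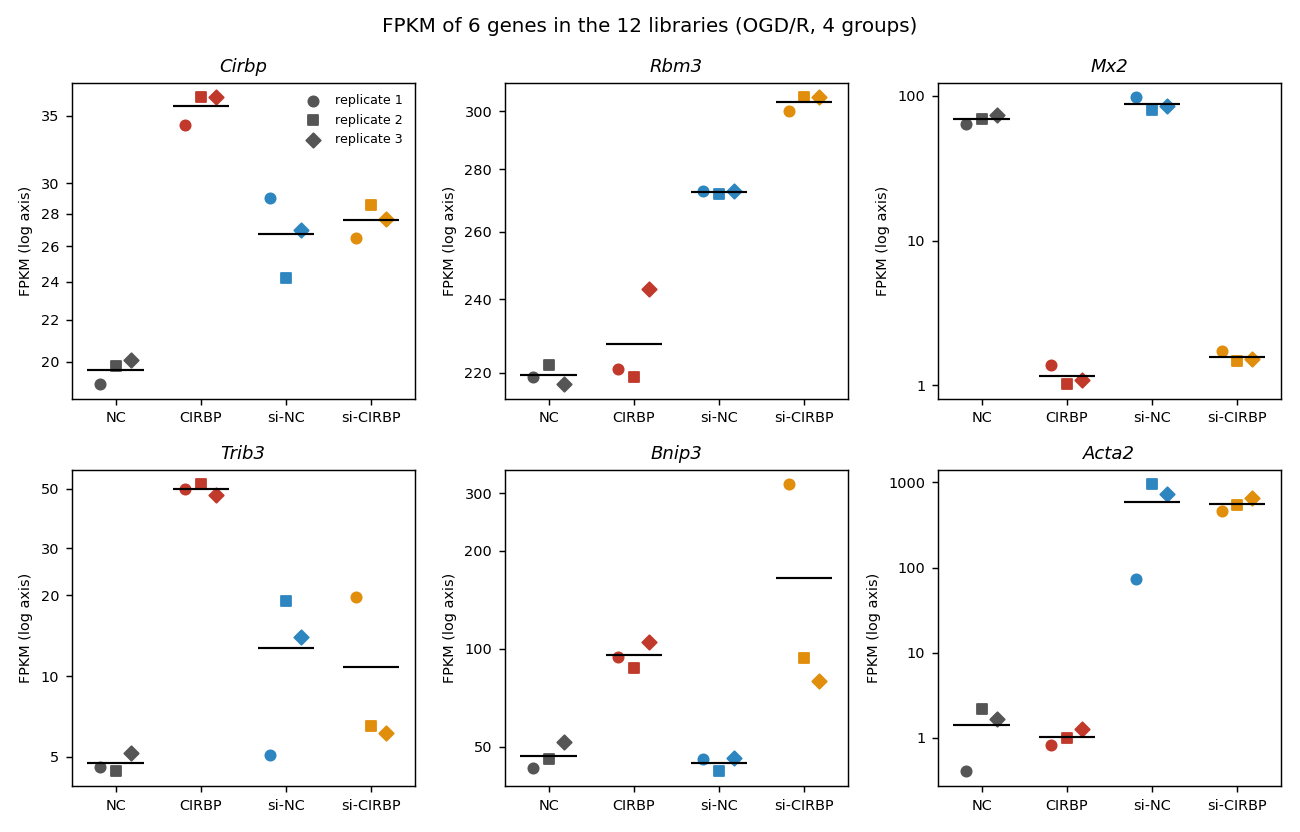
FPKM on a log axis of Cirbp, Rbm3, Mx2, Trib3, Bnip3 and Acta2 in the 12 libraries, with 1 point per library, its shape giving the replicate, and a black bar at each group mean. Cirbp is at 35.8 FPKM in CIRBP against 19.7 FPKM in NC but at 27.6 and 26.7 FPKM in si-CIRBP and si-NC, Mx2 is low in CIRBP and si-CIRBP, and si-NC library 1 holds less Acta2 than si-NC libraries 2 and 3.

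Part of the muscle markers separated the libraries by arm. Of the 9 smooth muscle markers, 4 had a mean under 1 FPKM in both NC and CIRBP and none in si-NC or si-CIRBP, and of the 18 skeletal and cardiac muscle markers, 9 did in NC and CIRBP and 2 in si-NC. Others were expressed throughout, such as Cald1, an actin-binding protein, at 185 ± 5.11 FPKM in NC and 226 ± 49.5 FPKM in si-NC, and the calcium pump Atp2a2, at 129 ± 1.32 and 143.5 ± 9.53 FPKM. Values per gene do not separate transcript forms, so whether Cald1 and Atp2a2 mark muscle cells here was not tested. In NC and CIRBP, Acta2, the smooth muscle actin, was at 1.41 ± 0.915 and 1.02 ± 0.220 FPKM. Myod1, the myogenic transcription factor, was there at 0.0414 ± 0.041 and 0.0504 ± 0.0255 FPKM. In si-NC and the libraries labelled si-CIRBP, Acta2 was at 583 ± 456 and 557 ± 97.2 FPKM and Myod1 at 12.9 ± 10.2 and 10.8 ± 0.894 FPKM. The si-NC libraries differed among themselves, with Acta2 at 73.8, 954 and 722 FPKM in libraries 1, 2 and 3. S100b, a calcium-binding protein abundant in astrocytes, was at 111 to 188 FPKM in all 12 libraries. The astrocyte filament gene Gfap was at 4.50 ± 0.252, 6.88 ± 0.00968, 1.90 ± 0.426 and 2.76 ± 0.887 FPKM in NC, CIRBP, si-NC and si-CIRBP. Vim and S100a4, which mesenchymal cells express, were abundant throughout, with Vim at 1930 to 2610 FPKM. Of the 3 macrophage, 4 endothelial and 2 epithelial markers tested, the highest in NC were the lipopolysaccharide co-receptor Cd14 at 10.9 ± 0.220 FPKM, Tie1 at 3.09 ± 0.318 FPKM and Epcam at 16.8 ± 0.568 FPKM.

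Against NC, 26 of 29 interferon response genes and 15 of 26 inflammation and NF-kB genes fell in CIRBP, and 9 of 14 genes of the amino acid response, 11 of 22 NRF2 targets, 12 of 21 cholesterol synthesis genes and 10 of 24 G2/M genes rose. These 6 lists were called by camera at its preset correlation, but none was called with the correlation estimated from the data (adjusted p = 0.424 to 0.583 with an estimated correlation). That correlation came from the residuals of all 12 libraries, so the wider spread within the si groups entered it here. It was not estimated from the NC and CIRBP libraries alone. Mx2, an interferon-induced GTPase, fell from 68.8 ± 4.62 to 1.16 ± 0.197 FPKM (log2 fold change -5.02, SE 0.0916, adjusted p = 3.98e-10). Gadd45b, a stress-induced growth arrest gene, fell from 379 ± 13.0 to 16.2 ± 0.627 FPKM (log2 fold change -4.46, adjusted p = 2.75e-05). Tnfaip3, the A20 inhibitor of NF-kB signalling, fell from 42.0 ± 1.17 to 2.14 ± 0.363 FPKM (log2 fold change -3.78). Trib3, a pseudokinase induced by amino acid and ER stress, rose from 4.73 ± 0.404 to 49.6 ± 2.36 FPKM (log2 fold change 3.14, adjusted p = 0.000162). Clec3b, which encodes tetranectin, rose from 4.92 ± 0.287 to 39.1 ± 3.61 FPKM (log2 fold change 2.76, adjusted p = 2.07e-08).

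Of 29 tested interferon response genes, 26 fell in CIRBP, 1 rose and 2 were not called. When adjusted over the list alone, 27 were called (camera adjusted p = 1.31e-09, but adjusted p = 0.424 with an estimated correlation). Irf9, a subunit of the interferon-activated ISGF3 complex, fell from 53.9 ± 1.31 to 10.4 ± 0.246 FPKM. The decrease of Xaf1 was from 29.1 ± 1.31 to 4.31 ± 0.226 FPKM and that of Ifi44 from 26.8 ± 1.52 to 4.08 ± 0.216 FPKM. The other large decreases included the interferon-induced Samd9, Rsad2, Rtp4 and Ifit3, with log2 fold changes of -4.37, -3.30, -3.25 and -3.24. Of 26 inflammation and NF-kB genes, 15 fell and none rose, 15 also when adjusted over the list alone (camera adjusted p = 0.00366, but adjusted p = 0.583 with an estimated correlation). Relb and Nfkb2, NF-kB subunits, fell from 45.9 ± 1.14 to 3.99 ± 0.310 FPKM and from 111 ± 1.70 to 17.6 ± 0.611 FPKM. Il1rl1, the IL-33 receptor, fell from 12.9 ± 1.36 to 1.49 ± 0.137 FPKM. Of 18 circadian clock genes, 12 fell and none rose, 12 also when adjusted over the list alone (camera adjusted p = 0.0145, but adjusted p = 0.583 with an estimated correlation). The clock repressor Nr1d1 fell from 206 ± 4.53 to 30.5 ± 2.15 FPKM and the clock output gene Dbp from 110.4 ± 4.89 to 53 ± 2.85 FPKM. Clock genes also fell between the control groups, 13 of 18 in si-NC against NC, Dbp among them. A fall of this list was thus not particular to CIRBP. The decreases in CIRBP also took in Kcnn1, a calcium-activated potassium channel (log2 fold change -3.10), and Gadd45g (-3.05).

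Of 14 genes of the amino acid response and one-carbon metabolism, 9 rose in CIRBP and 2 fell. When adjusted over the list alone, 11 were called (camera adjusted p = 0.000371, but adjusted p = 0.583 with an estimated correlation). The serine synthesis enzymes Phgdh, Psat1 and Psph rose from 54.6 ± 0.343 to 141 ± 1.84 FPKM, from 30.1 ± 0.668 to 105 ± 1.26 FPKM and from 20.3 ± 0.927 to 63.7 ± 2.77 FPKM. Shmt2, the mitochondrial serine hydroxymethyltransferase, rose from 35.5 ± 1.36 to 111 ± 1.40 FPKM. Slc7a11, the cystine transporter, and Pycr1, an enzyme of proline synthesis, rose with log2 fold changes of 2.50 and 2.55. Slc3a2, the partner chain of Slc7a11, fell (-0.43). Of 23 ER stress genes, 11 rose and 4 fell, 15 also when adjusted over the list alone (camera adjusted p = 0.0193, but adjusted p = 0.557 with an estimated correlation). The asparagine synthetase gene Asns rose from 27.1 ± 1.23 to 134 ± 9.56 FPKM and Chac1, which breaks down glutathione, from 6.12 ± 0.556 to 47.0 ± 1.19 FPKM. Among those that fell was Xbp1, a transcription factor of the unfolded protein response (log2 fold change -0.64). Of 22 NRF2 targets, 11 rose and 1 fell, 12 also when adjusted over the list alone (camera adjusted p = 0.000371, but adjusted p = 0.424 with an estimated correlation). The quinone reductase Nqo1 went from 79.5 ± 5.67 to 316.5 ± 26.0 FPKM. Stc2, Ddit4l2 and Tubb3 were among the other largest increases, at log2 fold changes of 2.34, 2.33 and 2.28. Tma7 gave the highest fold change, 4.47 (adjusted p = 0.00943). It is uncertain, since it also stood at 26.0 FPKM in si-NC library 1 and at 0.474 and 0.647 FPKM in si-NC libraries 2 and 3.

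Of 21 cholesterol synthesis genes, 12 rose in CIRBP and none fell, with 14 called when adjusted over the list alone (camera adjusted p = 2.48e-05, but adjusted p = 0.583 with an estimated correlation). Srebf2, the transcription factor that drives the pathway, rose from 28.0 ± 0.178 to 66.3 ± 3.92 FPKM and Dhcr7 from 11.4 ± 0.940 to 26.9 ± 3.57 FPKM. Of 24 G2/M genes, 10 rose and none fell, 10 also when adjusted over the list alone (camera adjusted p = 0.00013, but adjusted p = 0.583 with an estimated correlation). Of 25 DNA replication genes, 13 rose and none fell, with 14 adjusted over the list alone (camera adjusted p = 0.000515, but adjusted p = 0.583 with an estimated correlation). The mitotic kinase Cdk1 went from 62.9 ± 0.813 to 133 ± 1.90 FPKM. Aurkb, another mitotic kinase, went from 14.8 ± 0.400 to 25.6 ± 0.874 FPKM and the replication helicase factor Cdc45 from 2.61 ± 0.034 to 5.09 ± 0.382 FPKM. Of 6 neuron and oligodendrocyte markers, 5 rose and none fell, 5 also when adjusted over the list alone (camera adjusted p = 0.0123, but adjusted p = 0.424 with an estimated correlation). Of 7 astrocyte markers, 3 rose and none fell, 3 also when adjusted over the list alone (camera adjusted p = 0.0303, but adjusted p = 0.424 with an estimated correlation). The astrocyte markers that rose included Aldoc, which is counted in the glycolysis list too. Olig2, a transcription factor of oligodendrocytes, went from 2.64 ± 0.0476 to 5.07 ± 0.240 FPKM. Gfap rose with a log2 fold change of 0.52 (adjusted p = 0.0202), a call lost without NC library 2 (0.0637) or CIRBP library 1 (0.0518), 2 (0.0513) or 3 (0.0509).

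In further lists the number of members called depended on the scaling. Of 16 glycolysis genes, 4 rose and 1 fell, with 3 called when adjusted over the list alone (camera adjusted p = 0.0269, but adjusted p = 0.583 with an estimated correlation), against 10 higher and none lower after scaling to one median. Aldoc, a glycolytic aldolase, rose from 22.3 ± 1.59 to 87.4 ± 3.76 FPKM. Of 13 mitochondrially encoded genes, 5 rose and none fell, but 0 were called when adjusted over the list alone (camera adjusted p = 0.0139, but adjusted p = 0.583 with an estimated correlation). Mt-co2 rose from 3910 ± 138 to 6097 ± 164 FPKM. The rise of Mt-nd1, with a log2 fold change of 0.84, was lost without NC library 1, 2 or 3 (adjusted p = 0.0619, 0.0669 and 0.0595) or CIRBP library 1, 2 or 3 (0.0519, 0.0695 and 0.0655). Mitochondrial transcripts took 5.89 to 6.06% of the summed FPKM in the NC libraries and 7.82 to 8.29% in the CIRBP libraries. Among 23 p53 and apoptosis genes, 13 fell and 2 rose, 15 being called when adjusted over the list alone (camera adjusted p = 0.126). The p53 target Phlda3 fell from 338 ± 6.84 to 189 ± 4.38 FPKM. Among 13 ubiquinone synthesis genes, 8 fell and 1 rose, 9 being called when adjusted over the list alone (camera adjusted p = 0.146). Coq5, a methyltransferase of that pathway, fell from 20.8 ± 0.588 to 12.1 ± 0.270 FPKM. The hypoxia list had 4 of 22 members higher and 3 lower, 3 being called when adjusted over the list alone (camera adjusted p = 0.126). Hif1a, the hypoxia-inducible factor, fell from 69.4 ± 0.756 to 39.9 ± 0.802 FPKM. Nuclear-encoded OXPHOS genes had 6 of 28 members higher and 10 lower, a split that flips to 14 higher and 3 lower after scaling to one median and to 11 and 4 after scaling by median ratios (16 adjusted over the list alone, camera adjusted p = 0.642). The median of that list was -0.01, its mean 0.00 and the direction of camera upward. After scaling to one median, 8 mitochondrially encoded genes were higher and none lower, and the split of higher and lower members was 4 and 11 for p53 and apoptosis, 2 and 6 for ubiquinone synthesis and 6 and 2 for hypoxia.

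In all, limma called 7695 of 14257 tested genes at an adjusted p under 0.05 (54%), 2814 higher and 4881 lower in CIRBP. Of these, 308 and 788 had an absolute log2 fold change of at least 1. Scaling the libraries to one median moved the median log2 fold change of all genes from -0.08 to 0.03 and the split to 4095 higher and 3738 lower. Scaling by median ratios gave 3886 and 3921, so whether more genes rose or fell depends on the scaling. A fit of those 6 libraries alone called 10077 genes, 3978 higher and 6099 lower, of which 7676 were shared with the 7695. The median SD on the log2 scale was 0.0539 within NC and 0.057 within CIRBP. The labels call these libraries biological replicates, but whether they came from separate experiments is not given in the sources used here. If they did not, the spread behind these calls is that of cultures handled together. The calls would then not show whether a change recurs between experiments.

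Against si-NC, 26 of 29 interferon response genes and 14 of 26 inflammation and NF-kB genes fell in the libraries labelled si-CIRBP, and 17 of 21 cholesterol synthesis, 9 of 16 glycolysis and 12 of 22 hypoxia genes rose, although Cirbp itself was not lower there. None of these lists was called with the correlation estimated from the data (adjusted p = 0.228 to 0.722 with an estimated correlation), and the hypoxia genes of si-CIRBP library 1 stood at a median log2 ratio of 1.48 to libraries 2 and 3. Mx2 fell from 88.0 ± 9.22 to 1.57 ± 0.122 FPKM (log2 fold change -5.11, SE 0.0916, adjusted p = 3.29e-10) and Ifit3 from 30.1 ± 5.20 to 0.774 ± 0.440 FPKM (-4.15). Ccl5, an interferon- and NF-kB-driven chemokine, fell from 151 ± 37.6 to 13.2 ± 13.8 FPKM (log2 fold change -3.83, adjusted p = 0.000369). Clec3b rose from 1.67 ± 0.169 to 13.3 ± 1.45 FPKM (log2 fold change 2.42, adjusted p = 9.67e-08) and the immediate early gene Egr1 from 6.13 ± 1.95 to 34.8 ± 7.82 FPKM (log2 fold change 2.34, adjusted p = 3.12e-05).

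Of 29 interferon response genes, 26 fell in the libraries labelled si-CIRBP and none rose. When adjusted over the list alone, 27 were called (camera adjusted p = 6.23e-24, but adjusted p = 0.228 with an estimated correlation). Mx1 fell from 17.9 ± 1.87 to 0.409 ± 0.124 FPKM, Irf9 from 50.9 ± 3.99 to 9.13 ± 1.21 FPKM. Samd9, Rsad2, Oas1a, Dhx58 and Rtp4 fell with log2 fold changes of -3.89, -3.73, -3.46, -3.22 and -3.19. Of 26 inflammation and NF-kB genes, 14 fell and none rose, 14 also when adjusted over the list alone (camera adjusted p = 0.000475, but adjusted p = 0.722 with an estimated correlation). The chemokine Cxcl3 fell from 21.2 ± 3.65 to 0.952 ± 0.563 FPKM and Relb from 30.2 ± 5.01 to 11.3 ± 3.34 FPKM. Of 18 clock genes, 8 fell and none rose, 8 also when adjusted over the list alone (camera adjusted p = 0.0477, but adjusted p = 0.729 with an estimated correlation). Dbp fell from 49.6 ± 4.58 to 22.6 ± 1.72 FPKM.

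Of 21 cholesterol synthesis genes, 17 rose in the libraries labelled si-CIRBP and none fell. When adjusted over the list alone, 19 were called (camera adjusted p = 1.82e-10, but adjusted p = 0.689 with an estimated correlation). Srebf2 rose from 33.2 ± 2.96 to 52.9 ± 7 FPKM and Stard4, a sterol carrier, from 5.15 ± 0.240 to 9.66 ± 0.570 FPKM. Of 22 NRF2 targets, 8 rose and 1 fell, 10 being called when adjusted over the list alone (camera adjusted p = 0.00343, but adjusted p = 0.689 with an estimated correlation). Nqo1 rose from 78.9 ± 7.55 to 162 ± 4.46 FPKM. The member that fell was Nfe2l2, which encodes NRF2, from 105 ± 6.06 to 81.9 ± 1.71 FPKM. Of 25 DNA replication genes, 5 rose and none fell (3 adjusted over the list alone, camera adjusted p = 0.00262, but adjusted p = 0.729 with an estimated correlation). Of 28 nuclear-encoded OXPHOS genes, 9 rose and none fell (9 adjusted over the list alone, camera adjusted p = 0.00276, but adjusted p = 0.714 with an estimated correlation). Cytosolic ribosomal proteins had 4 of 30 members higher and none lower (1 adjusted over the list alone, camera adjusted p = 0.0123, but adjusted p = 0.729 with an estimated correlation). Astrocyte markers had 1 of 7 higher, Aldoc (1 adjusted over the list alone, camera adjusted p = 0.0454, but adjusted p = 0.568 with an estimated correlation). The amino acid response list had 2 of 14 members higher and 2 lower, 4 being called when adjusted over the list alone (camera adjusted p = 0.379). The scaling moved these counts, to 10 DNA replication, 15 OXPHOS and 10 ribosomal protein genes and 2 astrocyte markers higher and none lower after scaling to one median (6, 13, 8 and 2 by median ratios), and to 2 higher and 1 lower for the amino acid response with either.

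Of 22 hypoxia genes, 12 rose in the libraries labelled si-CIRBP and 1 fell, 15 being called when adjusted over the list alone (camera adjusted p = 6.54e-05, but adjusted p = 0.722 with an estimated correlation). The member that fell was Hif1a, from 56.7 ± 2.53 to 42.6 ± 1.41 FPKM. Of 16 glycolysis genes, 9 rose and none fell, 10 being called when adjusted over the list alone (camera adjusted p = 4.96e-05, but adjusted p = 0.689 with an estimated correlation). si-CIRBP library 1 stood apart in these genes. Bnip3, a hypoxia-induced mitophagy receptor, was at 320, 93.8 and 79.8 FPKM in libraries 1, 2 and 3 labelled si-CIRBP against 44.7 ± 2.39 FPKM in si-NC (log2 fold change 1.56, adjusted p = 0.0134). Ddit4, an inhibitor of mTORC1, was at 209, 28.5 and 28.8 FPKM against 11.7 ± 1.54 FPKM (2.17, adjusted p = 0.0186). In a fit of those 6 libraries alone the calls of Bnip3 (adjusted p = 0.106), Ddit4 (0.125), Adm (0.134), Ankrd37 (0.167), Pdk1 (0.0681), Pkm (0.0577) and Pgam1 (0.0931) were lost. The call of Ddit4 was also lost without si-NC library 3 (0.0502), that of Adm without si-NC library 1 (0.0525) or 3 (0.0634), and that of Ankrd37 without si-NC library 1 (0.0517), 2 (0.0853) or 3 (0.0969). The rises of Aldoc (log2 fold change 1.68, adjusted p = 0.000791), Apln (2.18, adjusted p = 0.000609), Scg2 (1.91) and Ppp1r3c (1.66) passed the test in that fit too.

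In all, limma called 4218 of 14257 genes in this arm (29.6%), 1294 higher and 2924 lower in the libraries labelled si-CIRBP. The split was 2424 and 1892 after scaling to one median, which moved the median log2 fold change from -0.04 to 0.06, and 1963 and 2287 after scaling by median ratios. A fit of those 6 libraries alone called 1155 genes, 266 higher and 889 lower. In simulated libraries the fit of all 12 called 310 of the unchanged genes in this comparison, 65.1% of its calls, against 24 (14.7%) for the fit of the 6, or 55.5% against 10% where the simulated SDs were moderated across genes. The median SD on the log2 scale was 0.133 and 0.147 within si-NC and si-CIRBP against 0.0539 and 0.057 within NC and CIRBP.

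The 2 arms moved mostly in the same direction, although Cirbp rose in only one of them (difference of the effects 0.78 on the log2 scale, SE 0.0922, adjusted p = 0.000577). Of the 3545 genes called in both arms, 926 rose in both, 2543 fell in both and 76 moved in opposite directions. Where each arm was fitted on its own libraries, 1084 genes were called in both in the same direction, against 3469 here, and the number was 1922 with a variance factor per group and 165 at an absolute log2 fold change of at least 1. The interferon genes Mx2, Samd9, Rsad2, Rtp4 and Irf9 fell in both arms, and Clec3b, Scg2, Egr1, Aldoc, Nqo1 and Srebf2 rose in both. Independent lists of these sizes would share 255.4 genes rising in both, and 1001 falling in both. For the opposite combinations the expected numbers were 577.1 and 443, and 42 and 34 were seen. Across all tested genes, which are not independent replicates, the log2 fold changes of the arms gave Pearson r = 0.668 and Spearman rho = 0.674. In 75% of genes they had the same sign. The arms have separate control libraries.

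**Figure D2:**
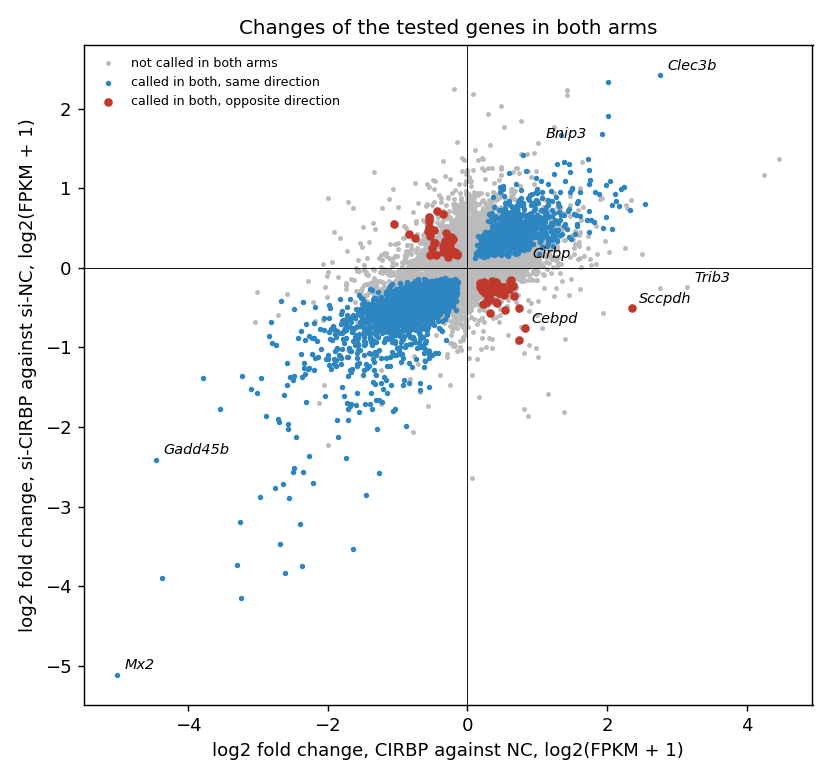
Log2 fold change of each tested gene in CIRBP against NC (horizontal axis) and in si-CIRBP against si-NC (vertical axis), on the log2(FPKM + 1) scale, with 1 point per gene. Blue points are the 3469 genes called in both arms in the same direction, red points the 76 called in opposite directions, and grey points the rest, with Mx2 low in both arms and Cirbp high on the horizontal axis alone.

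The arms differed in part of the amino acid response and ER stress genes. Of 14 genes of the amino acid response, 9 differed between the arms, all towards a higher value in the CIRBP arm (9 also when adjusted over the list alone, camera adjusted p = 2.02e-07, but adjusted p = 0.81 with an estimated correlation). Asns, which rose in CIRBP, was at 33 ± 4.25 FPKM in si-NC and 41.6 ± 18.2 FPKM in the libraries labelled si-CIRBP, and the effects differed by 2.01 on the log2 scale (SE 0.313, adjusted p = 0.00234). Psat1, Phgdh and Shmt2 differed by 1.18, 0.92 and 1.5. Atf4, which encodes the transcription factor of this response, differed by 1.09 (adjusted p = 0.00681), with a log2 fold change of 0.21 in CIRBP (adjusted p = 0.281) and of -0.88 in the libraries labelled si-CIRBP (adjusted p = 0.00174). Of 23 ER stress genes, 9 differed, all towards the CIRBP arm (10 adjusted over the list alone, camera adjusted p = 0.000566, but adjusted p = 0.81 with an estimated correlation). Among them were Trib3 and Chac1 with differences of 3.38 and 3.01. Of 22 NRF2 targets, 5 differed upward and 1 downward (6 adjusted over the list alone, camera adjusted p = 0.014, but adjusted p = 0.81 with an estimated correlation). Of 29 interferon genes, 8 differed upward and 1 downward (10 adjusted over the list alone, camera adjusted p = 0.000861, but adjusted p = 0.865 with an estimated correlation). For Mx1 and Ifit3 this was a smaller fall in CIRBP, by 1.37 and 0.91, from lower control values of 4.59 ± 0.281 and 10.4 ± 1.22 FPKM in NC. G2/M genes had 2 of 24 members higher and none lower (0 adjusted over the list alone, camera adjusted p = 2.32e-05, but adjusted p = 0.865 with an estimated correlation), against 4 after scaling to one median and 5 by median ratios. Mitochondrially encoded genes had 0 of 13 either way (0 adjusted over the list alone, camera adjusted p = 0.0117, but adjusted p = 0.875 with an estimated correlation). Hypoxia genes had 1 of 22 members lower and none higher (1 adjusted over the list alone, camera adjusted p = 0.116).

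Among genes called in opposite directions, Cebpd, a stress-induced transcription factor, rose from 10.3 ± 0.397 to 19.0 ± 2.15 FPKM in CIRBP and fell from 87.2 ± 6.50 to 51.2 ± 7.28 FPKM in the libraries labelled si-CIRBP, with effects that differed by 1.58 (SE 0.148, adjusted p = 0.000263). Bmp2, a growth factor of the TGF-beta family, rose from 9.38 ± 0.178 to 16.3 ± 1.15 FPKM in CIRBP and fell from 12.6 ± 1.41 to 8.56 ± 0.357 FPKM in the other arm (difference 1.24, SE 0.112, adjusted p = 0.000247). Sccpdh, Galnt3 and Casp4, an inflammatory caspase, rose in CIRBP and fell in the libraries labelled si-CIRBP, and Rab7b, Tspan33, Sh2d4a, Col8a2 and the metallothionein Mt1 did the opposite. In a fit of the 6 si libraries alone these 8 lost their call in that arm, with adjusted p = 0.131 for Sccpdh, 0.0754 for Galnt3, 0.114 for Casp4, 0.0895 for Rab7b, 0.0686 for Tspan33, 0.0888 for Sh2d4a, 0.164 for Col8a2 and 0.149 for Mt1. Single libraries also decided some of these calls. The fall of Sccpdh in the libraries labelled si-CIRBP was lost without si-NC library 1 (adjusted p = 0.0729) or 3 (0.0782) or si-CIRBP library 2 (0.0823) or 3 (0.0874). The rise of Col8a2 was lost without si-CIRBP library 1 (0.0523), 2 (0.0574) or 3 (0.115). The rise of Mt1 was lost without si-NC library 2 (0.125) or 3 (0.113) or si-CIRBP library 1 (0.123) or 3 (0.0724). The fall of Casp4 was lost without si-CIRBP library 2 (0.0533) or 3 (0.0569), and its rise in CIRBP without NC library 1 (0.0583) or 2 (0.06) or CIRBP library 1 (0.0566) or 2 (0.0738).

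In all, limma found a difference between the effects for 2535 of 14257 genes (17.8%), 980 higher and 1555 lower in the CIRBP arm, or 1309 and 1372 after scaling by median ratios. In simulated libraries the same fit called 69 unchanged genes, 33% of its calls, or 19.3% with moderated SDs. The count was 1650, 1673 and 1686 without NC library 1, 2 or 3, 1621 and 1596 without CIRBP library 1 or 2, and 4503 without si-CIRBP library 1. The count of opposite genes was 48 and 44 without NC library 1 or 2, 46 and 49 without CIRBP library 1 or 2, 223 without si-CIRBP library 1, and 11 where each arm was fitted on its own libraries.

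The 2 control groups differed from each other, with genes of muscle and connective tissue among the largest increases. No gene list was called between them by camera with an estimated correlation (lowest adjusted p = 0.393). Against NC, the si-NC libraries held more Acta2 (log2 fold change 7.35, SE 0.759, adjusted p = 0.000181), more Col1a1, the main chain of type I collagen (6.35, adjusted p = 0.00042), more of the muscle carbonic anhydrase Ca3 (7.13) and more of the myosin light chain Myl9 (6.31). Mir675 also rose (7.86, adjusted p = 0.002) but is uncertain, since it overlaps the H19 transcript. Fgfr3, a fibroblast growth factor receptor, fell from 28.9 ± 0.173 to 5 ± 1.08 FPKM (log2 fold change -2.34, adjusted p = 5.32e-06), and Spib, Olfml2a, Rgr and Kcnn1 fell with log2 fold changes of -1.84, -1.69, -1.65 and -1.56.

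Of 30 extracellular matrix and TGF-beta genes, 17 rose in si-NC against NC and none fell, with 20 called when adjusted over the list alone (camera adjusted p = 1.08e-09, but adjusted p = 0.547 with an estimated correlation). Of 9 smooth muscle markers, 6 rose and none fell, 7 being called when adjusted over the list alone (camera adjusted p = 2.8e-05, but adjusted p = 0.547 with an estimated correlation). Of 18 skeletal and cardiac muscle markers, 7 rose and 1 fell, 8 being called when adjusted over the list alone (camera adjusted p = 0.00028, but adjusted p = 0.547 with an estimated correlation). Tagln, a smooth muscle marker, rose from 1.80 ± 0.165 to 221 ± 171 FPKM, Casq2, a muscle calcium store protein, from 0.153 ± 0.0374 to 27.3 ± 22.6 FPKM. Ccn2, a TGF-beta target, rose from 144 ± 4.81 to 446 ± 63.8 FPKM. The si-NC libraries 1, 2 and 3 held 73.8, 954 and 722 FPKM of Acta2 and 42.4, 661 and 395 FPKM of Col1a1. Of 9 fibroblast markers, 4 rose and 2 fell, 8 being called when adjusted over the list alone (camera adjusted p = 0.178). Thy1 rose with a log2 fold change of 4.37 while S100a4 fell from 1752 ± 43.8 to 1132 ± 116 FPKM. Astrocyte markers had 1 of 7 members higher and 3 lower (5 adjusted over the list alone, camera adjusted p = 0.895), with Gfap falling (log2 fold change -0.94).

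Of 29 interferon genes, 16 rose in si-NC against NC and none fell, with 17 called when adjusted over the list alone (camera adjusted p = 3.06e-08, but adjusted p = 0.547 with an estimated correlation). Of 26 inflammation and NF-kB genes, 10 rose and 1 fell, 12 being called when adjusted over the list alone (camera adjusted p = 9.33e-05, but adjusted p = 0.577 with an estimated correlation). The monocyte chemokine Ccl2 rose from 70.2 ± 5.34 to 1624 ± 142 FPKM, Ccl5 from 5.73 ± 1.33 to 151 ± 37.6 FPKM, and B2m, the light chain of MHC class I, from 360.5 ± 17.6 to 703 ± 76.3 FPKM. Of 25 DNA replication genes, 13 rose and none fell (16 adjusted over the list alone, camera adjusted p = 2.04e-07, but adjusted p = 0.577 with an estimated correlation). Of 18 clock genes, 13 fell and none rose (15 adjusted over the list alone, camera adjusted p = 2.8e-05, but adjusted p = 0.577 with an estimated correlation). Dbp fell from 110.4 ± 4.89 to 49.6 ± 4.58 FPKM. Of 13 chaperones, 5 rose and none fell (9 adjusted over the list alone, camera adjusted p = 0.000851, but adjusted p = 0.393 with an estimated correlation). Of 23 ER stress genes, 5 rose and none fell (5 adjusted over the list alone, camera adjusted p = 0.00017, but adjusted p = 0.393 with an estimated correlation). Hspb1, a small heat shock protein, rose from 0.116 ± 0.0212 to 74.3 ± 59.1 FPKM. It was at 8.95, 124 and 89.9 FPKM in si-NC libraries 1, 2 and 3, so it differed within si-NC as Acta2 and Col1a1 did. Calr, an ER chaperone, rose from 359.5 ± 9 to 509 ± 42.8 FPKM. The amino acid response, cholesterol and ribosomal protein lists had 4 of 14, 6 of 21 and 7 of 30 members higher and none lower (4, 3 and 6 adjusted over the list alone, camera adjusted p = 0.00602, 0.000557 and 9.79e-05), each with adjusted p = 0.577 with an estimated correlation. G2/M and mitochondrially encoded genes had no member called (0 adjusted over each list alone, camera adjusted p = 0.00777 and 0.0305, but adjusted p = 0.715 and 0.655 with an estimated correlation). After scaling to one median 3 G2/M and 8 ER stress genes were higher, and 3 and 9 by median ratios, none of them lower. In CIRBP against NC, called clock genes fell too, and called DNA replication, cholesterol, amino acid response and ER stress genes mostly rose too. Called interferon, inflammation and chaperone genes mostly fell there, the other way. Both comparisons use the same NC libraries, so they are not independent.

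In all, limma called 4909 of 14257 genes between the control groups (34.4%), 1783 higher and 3126 lower in si-NC. The split was 2150 and 2475 after scaling to one median, 2174 and 2516 after scaling by median ratios, and 527 and 90 at an absolute log2 fold change of at least 1. In simulated libraries the same fit called 87 unchanged genes, 35.2% of its calls, or 18.5% with moderated SDs. A fit of those 6 libraries alone called 4503 genes, 3820 of them shared with the 4909. The count was 3107 without NC library 2, 3085 without si-NC library 3 and 8188 without library 1 of si-NC and of si-CIRBP. It was 315 with the mean of the smooth muscle markers as a covariate, which is nearly confounded with this contrast by construction. The covariate ended the calls of Mir675 (adjusted p = 0.664), Col1a1 (0.171), Ca3 (0.169), Olfml2a (0.0555), Rgr (0.317), Casq2 (0.996), Ccn2 (0.0515), Thy1 (0.817), S100a4 (0.307), Gfap (0.509), B2m (0.132) and Calr (0.258).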

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

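The tests of the Cirbp interval in the libraries labelled si-CIRBP were chosen only after the result was seen, and their limits were taken from the fit of the si groups alone after a first version had used the fit of all libraries. For 2535 genes the effects of the arms differed by a test of the difference itself. Of 100 splits of the libraries within the arms, 9 gave as many genes, with 7974 for the highest, which exchanges si-CIRBP and si-NC. All 9 are among the 11 splits drawn that keep the real CIRBP and NC groups. These hold the CIRBP effect by construction, and exchanging the si labels adds the effects of the arms, so the share over all 100 is no measure of chance for the difference and does not exclude it. The 83 splits that keep the real groups of neither arm called at most 1 gene with limma (up to 535 at an unadjusted p under 0.05). The 6 that keep those of the si arm alone called 0 (up to 1669). Splits that mix the real groups shrink a real effect and widen the spread within groups. Their low counts, here and below, are thus built in and do not argue against chance. For the other counts, 10 splits of 3 against 3 are too few for a share under 0.05, with 1 of 10 as large each time: 7695 genes in CIRBP against NC (highest other split 0 with limma, 127 at an unadjusted p under 0.05), 4218 in si-CIRBP against si-NC (highest other 73, or 2346 at an unadjusted p under 0.05) and 4909 in si-NC against NC (highest other 0 with limma, 1555 at an unadjusted p under 0.05).

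Cirbp differed between the arms by 0.7829 on the log2 scale, with a rise in CIRBP and no fall in the libraries labelled si-CIRBP. Cebpd differed by 1.581, Casp4 by 1.636, Galnt3 by 1.064, Sccpdh by 2.865 and Bmp2 by 1.238, each higher in CIRBP and lower in the libraries labelled si-CIRBP. Rab7b differed by -1.14, Tspan33 by -1.188, Col8a2 by -1.065, Sh2d4a by -0.947 and Mt1 by -1.269, each the other way round. Cebpd and Bmp2 kept both calls where each arm was fitted on its own libraries, and the other 8 lost the call in the si arm there. Groups of 3 libraries were not tested for single libraries far from the rest.

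The arms moved 3469 genes the same way and 76 in opposite directions, although one label names CIRBP and the other si-CIRBP. The lower 95% limit of the Cirbp change in the libraries labelled si-CIRBP was -0.163 on the log2 scale. It argues against silencing at the mRNA level. The upper limit, 0.263, argues against exchanged si-CIRBP and si-NC labels only if silencing had lowered the mRNA. Without such a loss, exchanged labels would also leave Cirbp alike in these groups, so an exchange stays open. A second cell type that follows the smooth muscle score is argued against as the source by the correlation of the arms. Across the 9693 genes that do not follow this score over the si libraries, it was 0.727. Over those libraries the score was low mainly in si-NC library 1, at 3.456 against 4.849 to 5.537 in the others. Cells of another type in different shares were not tested and stay open. The protein was not measured, so a change of CIRBP protein without one of its mRNA stays open. A response shared by both treatments that may not depend on Cirbp was not tested and stays open too. Both are hypotheses. How the cultures of each group were grown, treated and harvested is not given in the sources used here. A difference in handling between a group and its control would go with the label. It cannot be told apart from the treatment here and stays open as well.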

How the results depend on the processing

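The covariate, the variance factor per group, scaling by median ratios and leaving out library 1 of si-NC and of si-CIRBP together were tests chosen only after the data were seen. No list was called with an estimated correlation (0 in each of the 4 contrasts with camera, against 3, 2, 1 and 2 lists at an unadjusted p under 0.05 and lowest adjusted p of 0.424, 0.228, 0.81 and 0.393), and the other settings called 6 to 16 lists. CIRBP against NC gave 1096 genes at an absolute log2 fold change of at least 1, 6687 to 6816 with 1 library left out. For si-CIRBP against si-NC the count was 3253 to 5095 with 1 library left out, 2019 with a variance factor per group, 1155 with only the groups compared (1149 shared with the 4218), 2335 at an adjusted p under 0.01 and 239 at the fold threshold. For the difference it was 1596 to 4503 with 1 library left out (1650, 1673 and 1686 without NC library 1, 2 and 3, 1621 and 1596 without CIRBP library 1 and 2, 4503 without si-CIRBP library 1), 5899 without both libraries 1, 1079 at the stricter threshold and 279 at the fold threshold. Between the controls it was 3085 to 5894 with 1 library left out (3107 without NC library 2, 3085 without si-NC library 3), 8188 without both libraries 1, 315 with the covariate, 2398 at the stricter threshold and 617 at the fold threshold. For the 315, the covariate is nearly confounded with that contrast by construction; for the other changes, the cause was not tested.

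Opposite changes numbered 44 to 223 with 1 library left out (48 and 44 without NC library 1 and 2, 46 and 49 without CIRBP library 1 and 2, 223 without si-CIRBP library 1), 385 without both libraries 1, 138 with the covariate, 33 with a variance factor per group, 11 with only the groups compared, 19 at the stricter threshold and 0 at the fold threshold with limma (also 0 at an unadjusted p under 0.05). Shared changes numbered 2730 to 4107 with 1 library left out, 1922 with a variance factor per group, 1084 with only the groups compared, 2006 at the stricter threshold and 165 at the fold threshold. The correlation of the arms across genes was 0.609 without si-NC library 2, the lowest, and at most 0.669 with 1 library left out. Cirbp in the libraries labelled si-CIRBP gave 0.1649 after scaling to one median (adjusted p = 0.0435 with limma, against 0.0435 to 0.835 over the alternatives) and -0.018 to 0.109 with 1 library left out.

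Between the controls, 24 named genes reversed with the covariate, with log2 fold changes of -0.01192 for Lox, -0.7095 for Aldh1l2, -0.4973 for Slc7a11, -0.3786 for Cebpb, -0.6606 for Ptgs2, 0.09616 for Ncoa4, -0.8051 for Pmaip1, -0.548 for Mvd, -0.2953 for Fdps, -0.8533 for Acaa2, -0.3888 for Myod1, -0.8027 for Des, -0.687 for Pln, -0.2629 for Gja5, -0.5206 for Gja1, -0.377 for Cnn1, -0.8575 for Lmod1, -0.1234 for Thy1, -0.9239 for Lum, -0.774 for Slc1a3, -0.6051 for Mog, -1.158 for Eng, 0.08232 for Epcam and -1.001 for Krt8. Reversed means that a called gene changed sign, whatever its p with the covariate, so values near 0 as for Lox or Epcam are lost effects. The covariate, a mean of smooth muscle markers, is nearly confounded with this contrast by construction, so the changed signs are no evidence of reversed effects. No named gene reversed in the other settings run. Of the named values, 86 lost their call with only the groups compared, 43 with a variance factor per group, 78 with the covariate and 20 after scaling to one median. The FPKM hold no absolute depth, so what depth limits was not measured. The planned test for counts was not run, because the values were FPKM. Reads were not recovered from them, since FPKM steps depend on gene length.

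With the replicate number as a block, limma called 7512, 3926, 2232 and 4525 genes in the 4 contrasts (7406, 3816, 2138 and 4400 shared with the fit without it), and 11 named values lost their call. The labels share only a number: deviations of same-numbered libraries correlated at -0.0898 to 0.0995, and 8 of 12 libraries matched best with one of their own number, a hint from the data and not the design, so the libraries were not treated as paired.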

Other observations

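Of the tests below, the ratio within the set of 31 genes, both tests of the scaling, the second-type test in si-CIRBP and the glycolysis percentile were chosen only after the result was seen. In CIRBP against NC, heat shock and splicing genes held more falls than rises, by a margin that depended on the scaling. Of 13 chaperones, 5 fell and 1 rose (6 adjusted over the list alone, camera adjusted p = 0.202), with Cryab, the small heat shock protein of muscle and lens, going from 157 ± 7.74 to 63.3 ± 3.1 FPKM. Of 25 splicing factors, 13 fell and 1 rose (14 adjusted over the list alone, camera adjusted p = 0.199). After scaling to one median 3 chaperones fell and 2 rose and 10 splicing factors fell and 6 rose, and after scaling by median ratios 3 and 1 and 10 and 5. The transferrin receptor Tfrc fell from 45.0 ± 1.40 to 11.3 ± 1.65 FPKM (log2 fold change -1.91, adjusted p = 0.000116 with limma), and Hadhb, an enzyme of fatty acid oxidation, rose by 0.92 on the log2 scale. Tfrc and Hadhb were chosen after their values were seen.

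A set of 31 genes with a mean under 1 FPKM in NC and CIRBP and of at least 20 FPKM in si-NC, such as the muscle genes Ca3 (51.4, 741 and 498 FPKM in si-NC libraries 1, 2 and 3) and Tpm2 (18, 238 and 165 FPKM), stood at a median log2 ratio of -3.51 in si-NC library 1 to libraries 2 and 3 (quartiles -3.65 and -3.44). The scaling by the authors is argued against by the genes outside the set, whose median log2 ratio was 0.089. Cells of a second type in different shares remain open, with 93.5% of the set within a factor of 2 of the median ratio, as a change of one share would give. Outside the set 213 genes were at least 2-fold higher in si-NC libraries 2 and 3 than in library 1 and 33 at least 2-fold lower, a ratio of 0.155 lower to higher, which also goes with this hypothesis. A difference of the cultures in muscle differentiation may give similar ratios in the muscle genes and was not tested. The set was not limited to muscle genes: the fibroblast marker Thy1 stood at -3.74, while Lcn2 and Wfdc21 went the other way, at 0.549 and 0.313.

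The hypoxia genes of si-CIRBP library 1 stood at a median log2 ratio of 1.48 to libraries 2 and 3 of that label (22 members). The scaling by the authors is argued against by the median over all tested genes, -0.0267. A second cell type cannot be told apart by its own genes in that library, whose median log2 ratio was 0.13, but is argued against by the hypoxia list in si-NC, which stood at 0.0745 in library 1 to libraries 2 and 3 although the set above differed there. The 16 glycolysis genes stood at a median of 0.776 in si-CIRBP library 1 to libraries 2 and 3, above all of 10000 random lists (percentile 100). These random lists were matched on mean expression alone, while the glycolysis genes move together (estimated correlation 0.521). The percentile is thus no separate support for a cause. More oxygen deprivation in the culture of si-CIRBP library 1 is a candidate explanation, as a hypothesis found and tested on the same libraries.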
